A study of Homo sapiens with 1022 samples.

How the data were processed

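Single human cancer cells from mice carrying patient-derived xenografts (PDX), which are human breast tumors grown in mice, were assayed for a panel of 116 genes. The labels gave each of the 1022 cells its mouse, its xenograft model and the tissue it came from. Per the labels' protocols, tissue was digested with enzymes, and expression was read in single cells with an EvaGreen dye on the BioMark system, a microfluidic quantitative PCR instrument. Per the file headers, the deposited values were not normalized, with the raw threshold cycle (Ct) as the headers' example. The deposited values ran from 4.43 to 34, the range of a Ct, the PCR cycle at which the fluorescence of a gene crosses a set level. A lower Ct means more template. An empty entry was read as no Ct. The number of preamplification cycles, the limit of detection, the software that called Ct, and any filter on cells are not given in the sources used here. Of all gene and cell pairs, 46.7% had no Ct, and 28.7% of the deposited Ct values lay above 24. The table also had 57 unnamed columns, all of them empty. Of the 116 gene names, 114 were current symbols, 1 (FIGF) matched through an older name, and 1 (MLL4) fitted several genes and is given under the deposited name.

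The level of a gene in a cell was computed as 24 minus Ct, in cycles, with no Ct or a Ct above 24 set to 0. The limit of 24 was set before the data were examined, because the sources state none. A cycle is 1 unit on the log2 scale if PCR doubles the template at each cycle, which was not tested, so differences are given in cycles and no fold changes were computed. No gene of the planned list of 20 reference genes was on the panel. Cells were therefore not scaled to a reference gene, and the planned centring on reference genes, the planned restriction to cells with all of them, and their planned comparison between sites could not be run. A gene with no Ct in any cell of a mouse was treated as not measured in that mouse. By that rule 65 genes were measured in all 12 mice and 25 in a single mouse only, 22 of them in mouse 557 and 3 in mouse 599. In mouse 557, 27 genes had no Ct at all.

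Cells are not replicates, so levels were averaged over the cells of each mouse and tissue, and the mouse was the replicate. The 30 sets of cells from 1 mouse and 1 tissue held 4 to 96 cells, which limits the precision of each mean. Each mouse had its own run, so differences between runs and between mice cannot be separated. Comparisons within a mouse are free of both. Means were compared with limma (version 3.58.1, in R 4.3.3) with the mouse as a block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes had to be detected in at least 5% of the cells that entered a fit, counted over the mice in which they were measured. For lung against primary tumor, a gene also needed at least 3 mice with both tissues measured, and for the other tissues at least 2 (1 for blood where a mouse with blood cells was left out). That left 88 of 97 genes for lung against primary tumor. The difference between models was an F-test of the model by tissue interaction, and the differences within each model came from that fit, with a shared spread. Lymph node and blood differences came from a single fit of all tissues over 10 mice, with a spread shared by all tissues. A fitted difference there can depart from the plain difference of means, because the other tissues of a mouse enter its estimate. The primary tumors of the 3 models were compared by an F-test and by pairs over 10 mice.

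The mouse block rests on the labels, which place both tissues in 1 animal. As a check, each set's deviations from its tissue mean were correlated across genes between lung and primary tumor. The correlation within a mouse was 0.534 to 0.954, and the lung set of 8 of 9 mice correlated best with the primary set of its own mouse. The exception was mouse 552, at 0.534 with its own primary set and 0.724 with that of another mouse. Both sets of a mouse also share its run, so this check cannot tell a shared animal from a shared run. No cells had identical values.

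Gene lists were fixed before the data were examined. For each list and mouse, the lung minus primary difference was averaged over the tested members, and the 9 means were compared with 0 by an exact two-sided sign-flip permutation test, adjusted over the 10 lists. The smallest p this test can give with 9 mice is 0.00391. The spread between cells was the median over genes of the SD between the cells of a set, tested the same way, as was the median number of genes detected per cell. The rule for naming genes was also fixed. Genes past the threshold were named, and the genes of lowest p filled up to 10 per comparison, with up to 8 for the interaction and for each pair of models. Untested comparisons took up to 6 genes in each direction with a difference of at least 1 cycle, and fixed genes were always named for lung against primary tumor. Tissues found in 1 mouse, the mouse labelled as resected and the transplanted tumor were not tested. Their shares of cells have exact Clopper-Pearson 95% intervals, which cover counting error only.

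The fits were tested on simulated data made from the real means, with tissue or model labels swapped at random and a known shift added to 10 genes per shift size in each of 20 draws. Each shift was upward and the same in every mouse that received it. Recovery of falls, or of effects that vary between mice, was not tested. A shift of 1.5 cycles was found in 93.5% of cases for lung against primary tumor (88 genes) and a shift of 3 cycles in 100%. For HCI-010 alone (87 genes) the shares were 64.5% and 95.5%, and for the difference between models (87 genes) 37% and 79.5%. They were 79% and 98.5% for lymph node against primary tumor (89 genes), 86.5% and 100% for lung against lymph node (89 genes), and 63.5% and 95.5% for blood against primary tumor (83 genes). For the F-test of primary tumors, run on 88 genes, they were 23.1% and 49%, and for the pair HCI-010 minus HCI-001 25.1% and 51.5%. Genes given no shift were also called, at a mean of 0.5 per draw for lung against primary tumor, 2.3 for HCI-010 alone, 1.25 for the difference between models and 1.9 for blood. Each draw also held shifted genes, which loosens the Benjamini-Hochberg cut-off. These means are therefore not rates of false calls in data without shifts.

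Alternatives were the limit of detection, the share of cells with detection, means over detected cells, medians, centring each cell on its mean, other gene filters, removal of the 10% of cells with the fewest genes in each mouse, no mouse block, weights by cell number, the resected mouse added, each mouse left out, and other tests. A limit of 34, which keeps every deposited Ct, a setting with unmeasured genes at 0, a setting without mice 557 and 769, and the centring of cells for gene lists and for the spread were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.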

Results

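Expression of a gene panel was measured by quantitative PCR in 1022 single human cancer cells from 12 mice carrying patient-derived breast tumor xenografts. The mice belonged to 3 xenograft models, HCI-001 (3 mice, 224 cells), HCI-002 (4 mice, 351 cells) and HCI-010 (5 mice, 447 cells). Primary tumor cells came from 10 mice (391 cells), and 9 of these mice also gave lung metastatic cells (286 cells). Lymph node metastatic cells came from 4 mice (89 cells), peripheral blood cells from 2 mice (17 cells), bone marrow metastatic cells from 1 mouse (28 cells) and brain metastatic cells from 1 mouse (19 cells). A mouse labelled as resected added 48 primary and 48 lung cells, and a transplanted tumor added 96 cells. The title of the series names a stem cell program in metastatic cells, so metastatic cells were compared with the primary tumor cells of the same mouse. Levels are 24 minus the threshold cycle, averaged over the cells of a mouse and tissue. A cell had a median of 44 genes detected, and the medians of the 30 sets of 1 mouse and tissue ran from 29 to 59.5.

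At the main setting, mean levels of a pair of basal epithelial genes were higher in lung metastatic cells than in the primary tumor cells of the same mice. CDH3, which encodes the adhesion protein P-cadherin, rose by 0.80 cycles (SE 0.11, adjusted p = 0.00305, limma), from 4.71 ± 2.25 in primary tumors to 5.51 ± 2.22 in lungs (SD, n = 9), and was higher in 9 of 9 mice. KRT5, a keratin of basal cells, rose by 0.72 cycles (SE 0.15, adjusted p = 0.0282, limma), from 2.83 ± 1.57 to 3.54 ± 1.73 (SD, n = 9), again in 9 of 9 mice. CDH3 was detected in 91.1% of primary tumor cells and 95.2% of lung cells, and KRT5 in 77.6% and 85.7%, as means over mice. These were the 2 genes of 88 that passed. With the share of cells as the measure 0 genes passed, and 0 passed with the median over cells, detected cells only, a limit of 28 or 34, without the mouse block, or without the cells with the fewest genes. The fewest genes detected in any cell were 3 in primary tumor against 25 in lung in mouse 557. They were 11 against 23 in mouse 202, 12 against 24 in 769 and 14 against 21 in 22. The order was reversed in mice 549 (48 against 15), 552 (50 against 44) and D345 (32 against 30). In 929 and 599 they were 32 against 36 and 22 against 24. Cells with few genes lower the mean of a set, so a part of such cells in the differences is not excluded. An unadjusted p under 0.05 was found for 19 genes, against 4.4 expected by chance, and the difference was above 0 for 59 genes and below 0 for 29, with a median of 0.12 cycles.

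The named genes of stem cells, growth arrest and TGF-beta signaling did not pass on their own. The polycomb gene BMI1 differed by 1.38 cycles (SE 0.41, adjusted p = 0.136, above 0 in 7 of 8 mice) and LGR5, a Wnt-associated receptor of stem cells, by 0.77 cycles (SE 0.26, adjusted p = 0.143, above 0 in 9 of 9 mice). For BMI1 the difference was close to 0 in mice 769 (0.0153) and D345 (0.0108), and -0.26 in mouse 599. The difference was 0.44 cycles for POU5F1 and 0.15 cycles for SOX2, both pluripotency factors. TGFB2, a TGF-beta ligand, differed by 1.17 cycles (SE 0.37, adjusted p = 0.136) and the receptor TGFBR2 by 0.60 cycles (SE 0.16, adjusted p = 0.119), while TGFBR3 differed by -0.0135 cycles. CDKN1B, an inhibitor of the cell cycle, differed by 0.49 cycles, and SKP2, a ubiquitin ligase subunit that targets it for degradation, by 0.77 cycles. The survival gene BCL2 differed by 0.89 cycles (SE 0.39, adjusted p = 0.213, above 0 in 8 of 9 mice) and by 0.48 without mouse 202, the estrogen receptor gene ESR2 by 0.43 cycles and the transcription factor gene TWIST1 by 0.53 cycles. Of other genes fixed in advance, VIM, the mesenchymal filament vimentin, differed by -1.29 cycles (SE 0.49, adjusted p = 0.157, below 0 in 6 of 9 mice), MYC by -0.33, the epithelial cadherin CDH1 by -0.12, the luminal keratin KRT8 by -0.19 and the EMT factor SNAI2 by 0.0020 cycles. The sign changed without mouse 552 for MYC (0.0783) and TGFBR3 (0.0631), without mouse 202 for CDH1 (0.0369), TGFBR3 (0.0245) and SNAI2 (-0.12), and for SNAI2 also without mouse 929, 769 or D345. MKI67, KRT14 and KRT18 were measured in a single mouse and were not tested. With an exact sign-flip permutation test per gene, which cannot go below 0.00391 with 9 mice, the adjusted p was 0.115 for both CDH3 and KRT5 and 0 genes passed. With the resected mouse added neither passed (adjusted p = 0.117 for both, with 0.00226 to 0.999 for CDH3 and 0.0173 to 0.999 for KRT5 over all 27 alternatives). Without mouse 202, 929, 769, 599, 22, 552 or 549 in turn, CDH3 passed and KRT5 did not, which left 1 gene.

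**Figure D1:**
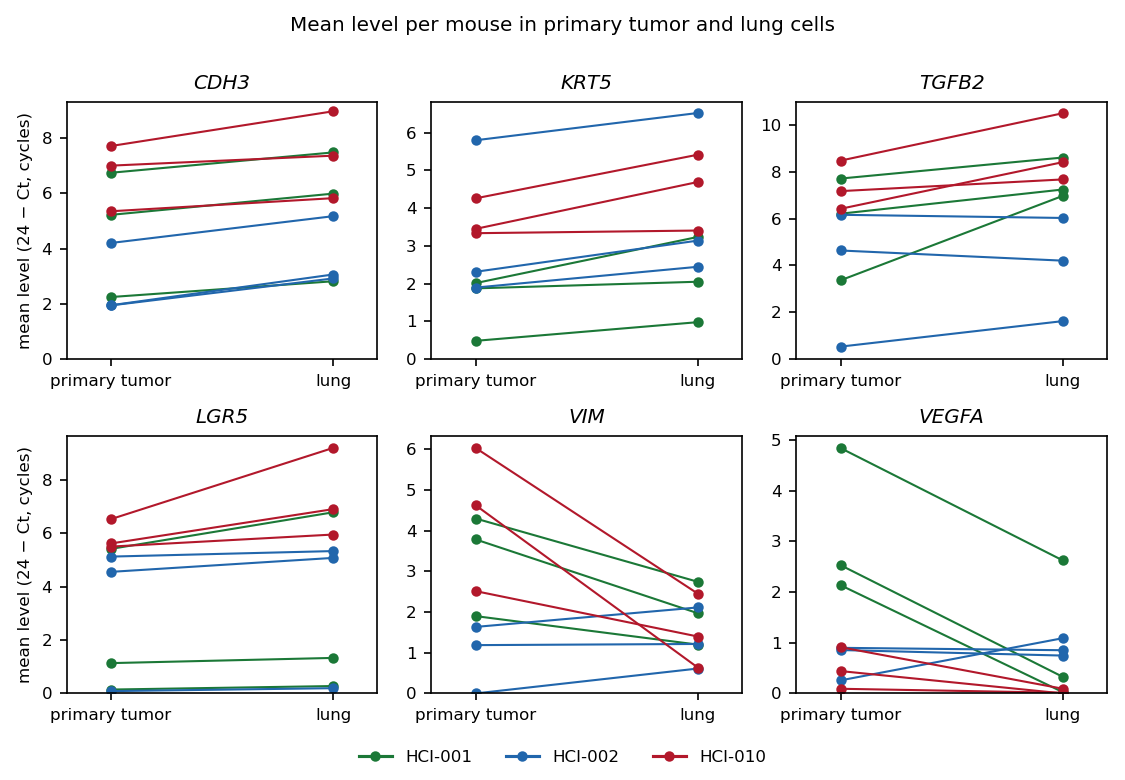
Mean level (24 minus Ct, in cycles) of 6 genes in primary tumor and lung cells, with a line for each of the 9 mice, colored by model. All 9 lines go up for CDH3 and KRT5, with mean differences of 0.80 and 0.72 cycles, whereas VIM was below its primary tumor level in 6 of 9 mice.

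By gene list, the stem cell list and the Notch, Wnt and Hedgehog list, of which no Hedgehog gene was tested, were shifted upward in lung cells. This holds on the scale without centring of cells. The median over all genes tested was itself 0.12 cycles. With each cell centred on its mean, an alternative chosen after seeing the data, these lists and the 3 other lists past the threshold no longer passed. Stem cell genes then had a mean of 0.23 (exact sign-flip adjusted p = 0.0977). The exact sign-flip adjusted p was 0.449 for the Notch, Wnt and Hedgehog list (mean 0.15) and 0.156 for quiescence genes (mean 0.36). It was 0.449 for survival genes and 0.458 for stromal markers, and the mean of each list stayed above 0. With a limit of 34, also chosen after seeing the data, the means were larger. They were 0.85 for stem cell genes, 1.16 for the Notch, Wnt and Hedgehog list, 0.90 for quiescence genes, 0.69 for survival genes and 1.30 for stromal markers. The 9 tested stem cell and pluripotency genes rose by a mean of 0.36 ± 0.23 cycles (SD, n = 9 mice; exact sign-flip p = 0.00391, the smallest possible, adjusted p = 0.0195), in 9 of 9 mice. Of its members 8 were above 0 and 1, CD44, was below 0 at -0.40 cycles, and 0 members passed limma over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. Mouse 769 was nearest 0, at a stem cell list mean of 0.020 cycles. BMI1, SOX2 and POU5F1 were not measured in mouse 557, nor POU5F1 in mouse 769. The mice therefore do not all average the same genes. The 4 tested members of the Notch, Wnt and Hedgehog list were NOTCH3, NOTCH4, JAG1 and WNT2, with no Hedgehog gene among them. These 4 genes rose by a mean of 0.28 ± 0.35 cycles (exact sign-flip adjusted p = 0.0195, from 0.0130 to 0.449 over the alternatives), in 9 of 9 mice. Mouse D345 was nearest 0, at 0.0073 cycles, and WNT2 was not measured in mouse 557. Without mouse 549 the mean was 0.18, and with the resected mouse added it was 0.24 and did not pass (exact sign-flip adjusted p = 0.0635). None of them passed limma over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. The 4 quiescence and cell cycle inhibition genes rose by 0.49 ± 0.32 cycles (exact sign-flip adjusted p = 0.0260), in 8 of 9 mice, with 0 members past limma over all genes and 2, TGFB2 and CDKN1B, past it adjusted over the list alone. It did not pass without mouse 929, 599, 22, 552, 549 or D345 in turn (exact sign-flip adjusted p = 0.0521 each, with means of 0.42 to 0.55 over all mice left out). The 4 survival and apoptosis genes rose by 0.39 ± 0.52 cycles (exact sign-flip adjusted p = 0.0469), in 7 of 9 mice, with BCL2 and BCL2L1 at 0.89 and 0.68 cycles and AKT1 at 0.0165, and 0 members past limma over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. It passed in 8 of 20 alternatives, was 0.24 without mouse 202 (exact sign-flip adjusted p = 0.0781), and did not pass without mouse 929, 599, 22, 552, 549 or D345 either (0.0625 to 0.0938).

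The list for blood, endothelial and stromal cells, with COL1A2 and THY1 as its 2 tested members, rose by a mean of 0.28 ± 0.26 cycles (exact sign-flip adjusted p = 0.0293), in 8 of 9 mice. Of its members, 0 passed limma over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. That list did not pass without mouse 929, 599, 22, 552, 549 or D345 in turn (exact sign-flip adjusted p = 0.0586 each, with means of 0.23 to 0.29). THY1 also belongs to the stem cell list. The basal list as a whole did not pass (0.15 ± 0.38 cycles, exact sign-flip adjusted p = 0.446, 6 of 9 mice above 0), although CDH3 and KRT5 were past limma over all genes and adjusted over the list alone, with ITGB1 at -1.01 cycles. Without mouse 599 the basal list differed by 0.0456 cycles. The luminal list differed by -0.0540 ± 0.38 cycles (exact sign-flip adjusted p = 0.751, 0 members past limma either way and 0 of 17 at an unadjusted p under 0.05), and by 0.0345 without mouse 552. The EMT and mesenchymal list differed by 0.0895 ± 0.15 cycles (exact sign-flip adjusted p = 0.195) with a median member of -0.0058, and TGFB2 and TGFBR2 were its 2 members past limma adjusted over the list alone. The proliferation list differed by 0.0439 ± 0.49 cycles (exact sign-flip adjusted p = 0.801), with CDK1 at 0.31 cycles, by -0.0353 without mouse 599, and by 0.78 with a limit of 34 (exact sign-flip adjusted p = 0.218). The hypoxia, angiogenesis and chemotaxis list differed by -0.26 ± 0.84 cycles (exact sign-flip adjusted p = 0.557), with a median member of 0.0937 cycles and VEGFA at -0.80 cycles. Without mouse 557, where VEGFA was the 1 tested member with a Ct, that list differed by -0.0187 cycles.

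**Figure D2:**
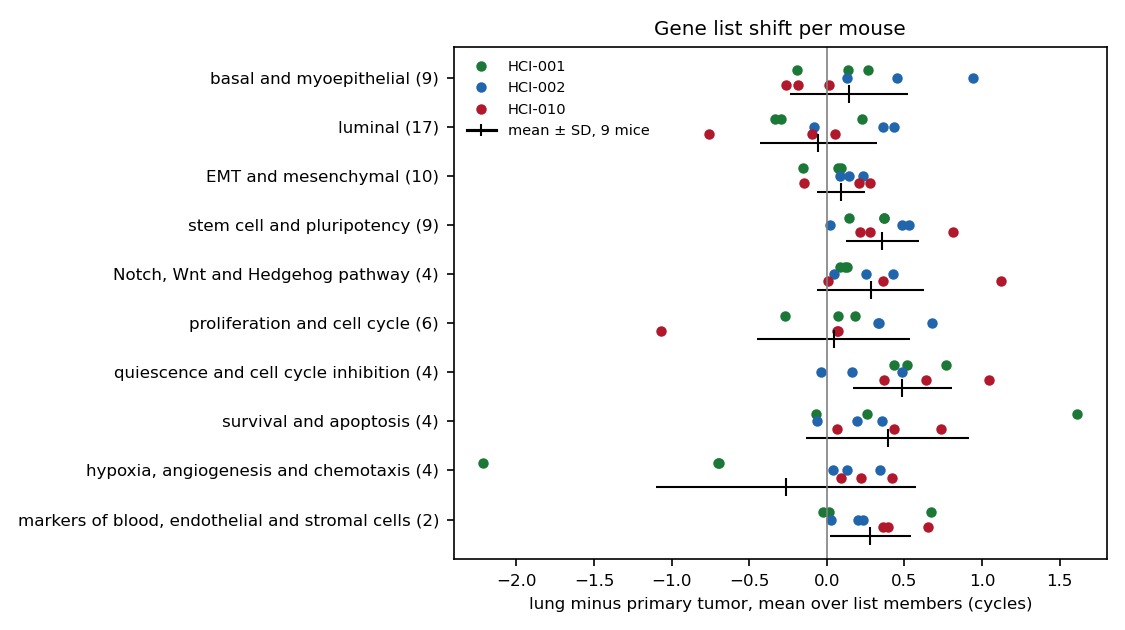
Lung minus primary tumor difference averaged over the tested members of each gene list (number of members in brackets), in cycles, with a point per mouse colored by model and a black bar for the mean ± SD of the 9 mice. The stem cell list (0.36 ± 0.23) and the Notch, Wnt and Hedgehog list (0.28 ± 0.35, no Hedgehog gene tested) lie above 0 in 9 of 9 mice. Their lowest values were 0.020 (mouse 769) and 0.0073 (mouse D345).

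Within single models, VEGFA was lower in HCI-001 lung cells than in the primary tumor, and VIM and EMP1 were lower in HCI-010 lung cells. The difference between models passed for VEGFA alone. In HCI-001, VEGFA, an angiogenic growth factor, fell by 2.17 cycles in lung cells (SE 0.23, adjusted p = 0.000827, limma, lower in 3 of 3 mice), from 3.17 ± 1.46 to 0.99 ± 1.42 (SD, n = 3). Its difference was 0.22 cycles in HCI-002 and -0.45 cycles in HCI-010, and VEGFA was the 1 gene of 87 whose difference itself differed between models (limma F-test, adjusted p = 0.0156, 9 genes at an unadjusted p under 0.05). That count was 0 with a limit of 22, 26 or 34, with the share of cells, without the mouse block, or without mice 557 and 769. The limit of 34 and the removal of both mice were chosen after seeing the data. In simulated data 1.25 genes per draw that had been given no shift were called for the difference between models, in draws that also held shifted genes. The count within HCI-001 was 0 with the share of cells, with a limit of 34, or without the mouse block. In HCI-010, VIM fell by 2.89 cycles (SE 0.49, adjusted p = 0.0256, limma, lower in 3 of 3 mice), from 4.39 ± 1.77 to 1.50 ± 0.91 (SD, n = 3), and EMP1, an epithelial membrane protein gene, fell by 2.86 cycles (SE 0.59, adjusted p = 0.0439, limma, lower in 3 of 3 mice), from 5.21 ± 1.57 to 2.35 ± 0.26. VIM was detected in 88.9% of HCI-010 primary tumor cells and 52.0% of lung cells, as means over mice. The count of 2 in HCI-010 was 0 with the share of cells, with weights by cell number, or without the mouse block. In simulated data 2.3 genes per draw that had been given no shift were called in HCI-010. Those draws also held shifted genes, so the value cannot be compared directly with the real count.

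Other named genes of HCI-010 did not pass. MYC differed by -2.04 cycles (adjusted p = 0.0674), below 0 in 3 of 3 mice. The differences were above 0 in 3 of 3 mice for the ephrin receptor EPHA4 (1.07 cycles), the IGF-binding protein IGFBP6 (1.08), the peptidase MME (0.98), LGR5 (1.47), TGFBR2 (0.94), CDH3 (0.70) and TP73 (1.32), at adjusted p values from 0.0674 to 0.0969. In HCI-001 the remaining named genes, none of which passed, included ZEB1 at -1.33 cycles and BMI1 at 2.73 cycles (each 2 mice, adjusted p = 0.0836), CDH3 at 0.69, TGFB2 at 1.84, VIM at -1.36, IGF1R at 1.02, TGFBR1 at -0.99, BCL2 at 1.55 (4.15, -0.0385 and 0.54 in mice 202, 929 and 557) and KRT5 at 0.63 cycles. In HCI-002, 0 of 87 genes passed limma and 3 had an unadjusted p under 0.05. CDH3 differed there by 1.02 cycles (SE 0.21, adjusted p = 0.0813) and KRT5 by 0.70 cycles, and the other named genes were TP63 (0.62), EPCAM (0.55), EMP1 (1.32), MMP1 (0.96), CDK1 (0.48), SKP2 (0.89), CCNE1 (0.84) and PARP1 (0.88). The differences between models were not past the threshold for EMP1 (adjusted p = 0.116), VIM (0.127), ZEB1 and MYC (both 0.193), CAV2 (0.423), MUC1 or EPHA4 (both 0.470). These calls rested on 3 mice per model: the count in HCI-010 went from 2 to 14 without mouse D345, to 0 without 552 or 549, to 0 without 202, 929 or 22, and to 1 without 557. Leaving out an HCI-010 mouse leaves 2 mice of that model, while the mice of other models enter its count through the shared spread and the genes tested. The count for HCI-001 went from 1 to 2 without mouse 929 and to 3 without D345, that for HCI-002 from 0 to 1 without 549, and that for the difference between models from 1 to 0 without 202, 929 or 557, to 2 without 769 and to 6 without D345.

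**Figure D3:**
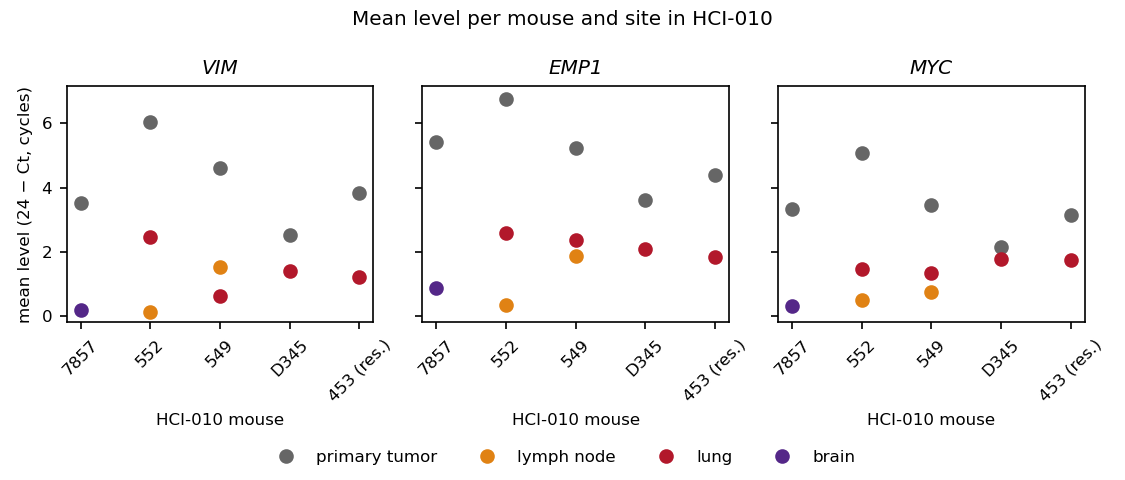
Mean level (24 minus Ct, in cycles) of VIM, EMP1 and MYC in each of the 5 HCI-010 mice, with a point per tissue. Primary tumor cells lie above the lung, lymph node and brain cells of the same mouse for all 3 genes, the mouse labelled as resected (453) included. Averaged over mice 552, 549 and D345, the lung minus primary tumor difference was -2.89 cycles for VIM, -2.86 for EMP1 and -2.04 for MYC.

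Lymph node metastatic cells were compared with primary tumor cells in 4 mice, and 0 of 89 genes passed limma, with 6 at an unadjusted p under 0.05. VIM had the lowest p, at 1.18 ± 0.97 against 3.55 ± 2.14 in primary tumors (SD, n = 4), a fitted difference of -2.04 cycles (SE 0.76, adjusted p = 0.550, below 0 in 3 of 4 mice). The glycoprotein genes MUC1 and CD44 differed by -1.28 and -0.70 cycles, EMP1 by -1.89, MYC by -1.30, the DNA repair gene PARP2 by -0.61 and the luminal factor GATA3 by -0.23 cycles. LGR5 differed by 0.94 cycles, above 0 in 4 of 4 mice, EPHA4 by 0.64 and BMI1 by 1.32 cycles. All of these had an adjusted p of 0.550. In mouse 552 the difference reached -5.92 cycles for VIM and -6.41 for EMP1, and in mouse 22 it was 0.73 and 0.57. Node cells of mouse 552 had a median of 46 genes detected, against 59.5 in its primary tumor cells, with 36 against 39 in mouse 22, 54 against 58 in mouse 549 and 30 against 29 in mouse 557. Of all 89 genes, 57 were below 0.

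Lung cells were set against lymph node cells of the same 4 mice to see whether sites of spread differed. No gene passed (0 of 89, limma), and 5 had an unadjusted p under 0.05. CDH3 was 0.62 cycles above the node level (SE 0.20, adjusted p = 0.517, 4 of 4 mice), with means of 5.51 ± 3.12 in lung and 4.89 ± 3.62 in node (SD, n = 4). The Notch receptor NOTCH3 differed by 0.53 cycles (SE 0.18, adjusted p = 0.517, 4 of 4 mice). The other named genes were THY1 (0.52 cycles), the neurotrophin receptor NTRK2 (0.48), the MYC partner MAX (0.25), the growth factor receptor IGF1R (0.61), the collagen gene COL1A2 (0.37), the cell cycle kinase CDK1 (0.34), the epithelial marker EPCAM (0.47) and the collagenase MMP1 (0.66). Of all 89 genes, 79 were above 0 and 10 below, with a median of 0.23 cycles, and without mouse 549 the count past the threshold was 1. More genes were detected per cell in lung than in node in each mouse, at medians of 35, 38.5, 54 and 56 against 30, 36, 46 and 54.

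In tumor cells from peripheral blood of 2 HCI-002 mice, JAG1 and KRT5 passed against primary tumor cells, a count of 2. The count was 0 with a limit of 22, with the share of cells, or without the mouse block. In simulated data 1.9 genes per draw were called without a shift. Those draws also held shifted genes, so the value cannot be compared directly with the real count. JAG1, a Notch ligand, rose by 1.78 cycles (SE 0.40, adjusted p = 0.0344, limma), with means of 1.74 ± 0.38 in primary tumor and 3.45 ± 1.57 in blood (SD, n = 2). KRT5 rose by 1.48 cycles (SE 0.35, adjusted p = 0.0344, limma), with means of 2.11 ± 0.30 and 3.57 ± 1.37. Both were higher in 2 of 2 mice, by 2.55 and 0.86 cycles for JAG1 and by 2.22 and 0.70 cycles for KRT5. The SE and p of both genes take the spread from all tissues in the fit. They do not measure the spread between the 2 mice with blood cells. The other named genes of the 83 tested did not pass: TWIST1 differed by 1.30 cycles and ESR2 by 0.81 (both adjusted p = 0.114), TGFBR2 by 1.34, NOTCH3 by 0.57, LGR5 by 1.13, TGFB2 by 1.35, CDK1 by 0.51 and the cyclin gene CCNE1 by -0.96 cycles. The plain differences in mice 769 and 599 were 0 and 2.55 for TGFBR2, -0.0867 and 1.94 for LGR5, and 0.0066 and 1.24 for TGFB2. TGFBR2 was detected in 0% of the cells of mouse 769. The fitted values of TGFB2 and CCNE1 lie outside those of both mice, at -0.23 and -0.79 for CCNE1. The blood set of mouse 599 held 4 cells and that of mouse 769 held 13, and no gene passed (0 genes) when means were weighted by cell number. Without mouse 929, 1 gene passed, and without mouse 552 or 549, 0 passed. Without mouse 769, 1 gene passed. Blood then comes from 1 mouse, which is assumed to vary like the other tissues, and the genes measured in that mouse are tested.

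Bone marrow metastatic cells of a single HCI-002 mouse (28 cells, against 24 primary tumor cells) were higher by 1 cycle or more for 7 of 77 genes and lower for 1. No test was run on this 1 mouse, and the values describe that mouse. TGFBR2 was 2.65 cycles above the primary tumor, at 3.90 against 1.25, and was detected in 82.1% of marrow cells (exact 95% interval 63.1% to 93.9%) and 33.3% of primary tumor cells (15.6% to 55.3%). In lung cells of the same mouse the TGFBR2 difference was 0.94 cycles. BMI1 was 2.04, the receptor gene ERBB2 1.93, the kinase gene ITPKB 1.62, LGR5 1.55 and TGFB2 1.55 cycles above the primary tumor level. ZEB1, a repressor active in EMT, lay at 0.92 against 2.12 in primary tumor, a difference of -1.20 cycles.

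Brain metastatic cells of a single HCI-010 mouse (19 cells, against 67 primary tumor cells) differed in both directions, with 16 of 82 genes higher and 17 lower by 1 cycle or more, and no test was run. LGR5 was 4.21 cycles above the primary tumor (6.15 against 1.94) and was detected in 100% of brain cells (exact 95% interval 82.4% to 100%) and 50.7% of primary tumor cells (38.2% to 63.2%). BMI1 was 4.12, TGFB2 3.98, the survival gene BCL2L1 3.30, CDH3 2.97 and CDKN1B 2.85 cycles above it. EMP1 was at 0.87 against 5.41, a difference of -4.54 cycles. The growth factor receptor FGFR2 differed by -3.95, VIM by -3.33, MYC by -3.02 and OLR1 by -2.82 cycles. The integrin gene ITGB1 differed by -3.52 cycles and was detected in 0% of brain cells (exact 95% interval 0% to 17.6%) and 80.6% of primary tumor cells (69.1% to 89.2%). Those brain cells had a median of 38 genes detected, against 45 in the primary tumor cells.

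The HCI-010 mouse labelled as resected showed no gene of 79 at least 1 cycle higher in lung cells (0 genes) and 8 at least 1 cycle lower, from 48 cells of each tissue and without a test. Its lung cells had a median of 40 genes detected, against 48 in its primary tumor cells. VIM lay at 1.21 in lung and 3.83 in primary tumor, a difference of -2.62 cycles, beside -3.58, -3.99 and -1.11 cycles in the 3 other HCI-010 mice with lung cells. EMP1 differed by -2.55, beside -4.17, -2.86 and -1.55 in those mice, and MYC by -1.39, beside -3.60, -2.13 and -0.39. CAV2, a caveolin, ITGB1 and MUC1 differed by -2.33, -2.08 and -1.46 cycles. VIM was detected in 43.8% of lung cells (exact 95% interval 29.5% to 58.8%) and 93.8% of primary tumor cells (82.8% to 98.7%).

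The transplanted HCI-002 tumor (1 mouse, 96 cells) had higher levels than all primary tumors of the 3 other HCI-002 mice for 43 of the 81 genes compared, again without a test. Its level was within the range of those 3 tumors for 35 genes and below it for 3, with a median difference of 1.31 cycles from their mean. The caveolin CAV1 was at 7.20 against a mean of 1.03, and TGFB2 at 9.59 against 3.78. SKP2 was 5.29, EPHA4 5.07, IGFBP6 4.97 and THY1 4.61 cycles above the mean of those tumors. CDK2, a cell cycle kinase, was 0.41 against 1.71, within their range. The 3 genes below the range, named after their values were seen, were CHEK1 (-0.14 cycles from the mean), TP73 (-0.21) and ERBB2 (-0.35). Its cells had a median of 57 genes detected, against 32 to 39 in the primary tumors of the other HCI-002 mice, and the run differed between all mice.

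Primary tumors of the 3 models were compared over 3, 3 and 4 mice, and 0 of 85 genes passed limma, with 8 at an unadjusted p under 0.05 (without mouse 929 or 599 the count past the threshold was 1, and without 557 it was 2). VEGFA was at 3.17 ± 1.46 in HCI-001 (SD, n = 3), 0.67 ± 0.36 in HCI-002 (n = 3) and 0.37 ± 0.40 in HCI-010 (n = 4), with an adjusted p of 0.312. Among the genes of lowest p, none past the threshold, THY1 was at 1.86 ± 0.89 in HCI-010, against 0.31 and 0.17 in HCI-001 and HCI-002, TWIST1 at 1.96 ± 0.63, VIM at 4.17 ± 1.51 and COL1A2 at 1.31 ± 0.19 in HCI-010, all at an adjusted p of 0.335. EMP1, VEGFC and CDH3 were at 5.26 ± 1.28, 1.84 ± 0.60 and 6.23 ± 1.35 in HCI-010, at adjusted p values of 0.388, 0.437 and 0.437.

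By pairs of models, 0 genes passed limma in each, with 5 at an unadjusted p under 0.05 for HCI-010 against HCI-001, 16 for HCI-010 against HCI-002 and 4 for HCI-002 against HCI-001. HCI-010 minus HCI-001 was -2.80 cycles for VEGFA (SE 0.62, adjusted p = 0.137), 1.55 for THY1, 0.90 for COL1A2, 1.43 for TWIST1, 3.48 for BCL2, 1.00 for NOTCH3, 1.13 for the smooth muscle actin gene ACTA2 and 1.47 for MME. HCI-010 minus HCI-002 was 3.23 cycles for VIM (SE 0.91, adjusted p = 0.158), 1.69 for THY1, 1.64 for TWIST1, 1.42 for VEGFC, 3.97 for EMP1, 3.53 for CDH3, 0.84 for COL1A2 and 2.01 for ZEB1. HCI-002 minus HCI-001 was -2.50 for VEGFA (SE 0.66, adjusted p = 0.401), -3.03 for ITGB1, -2.39 for VIM, -2.20 for the integrin gene ITGA6, -3.63 for EPCAM, -1.15 for CD44, 2.19 for JAG1 and -2.65 cycles for EMP1. EPCAM was at 0.19 in the primary tumor of mouse 769, 6.97 in mouse 599 and 1.85 in mouse 22. ZEB1 and VEGFC were at 0 in that of mouse 769. EPCAM, ZEB1 and VEGFC also had no Ct in mouse 557, so the model differences of these genes may carry the runs of mice 557 and 769. In simulated data, HCI-010 against HCI-001 found 25.1% of shifts of 1.5 cycles and 51.5% of shifts of 3 cycles, so differences of these sizes could go undetected.

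No difference in how alike the cells were was detected between lung and primary tumor. The median SD between cells was 1.13 ± 0.32 cycles in lung and 1.08 ± 0.31 in primary tumor (SD, n = 9), a difference of 0.0520 ± 0.30 (exact sign-flip p = 0.625, above 0 in 5 of 9 mice), and -0.0152 without mouse 599. The median number of genes detected per cell was 43.8 ± 8.96 in lung and 43.8 ± 11.4 in primary tumor, a difference of 0.0556 ± 3.30 genes (exact sign-flip p = 1, above 0 in 4 mice and below 0 in 4), and -0.688 and -0.375 genes without mouse 557 and mouse 599. With a limit of 34, chosen after seeing the data, the number of genes differed by 3.06 and passed (exact sign-flip p = 0.0469), and the spread differed by -0.0667.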

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

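The tests of explanations for VIM and EMP1 were chosen only after the result was seen, and the counts over other splits of the mice were planned.

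In 6 of 50 sets of values per mouse (lung minus primary differences, and primary levels in HCI-010), a single mouse stood apart from the others, against 2.5 expected by chance at about 1 in 20 sets. The sets overlap, since the list means contain named genes such as BCL2, so an excess over chance cannot be read from this count. All 6 were lung minus primary differences. Mouse 549 had the highest difference for LGR5 (2.66 cycles, the next being 1.37), for CDKN1B (1.71, the next being 0.71) and for the Notch, Wnt and Hedgehog list (1.12, the next being 0.42). Mouse 202 had the highest difference for BCL2 (4.15 cycles, the next being 1.21) and for the survival list (1.61, the next being 0.73). Mouse 557 had the lowest difference for the hypoxia, angiogenesis and chemotaxis list, at -2.21 cycles, the next being -0.70. VEGFA was the 1 tested member of that list with a Ct in mouse 557. The VEGFA difference itself was similar in the other HCI-001 mice, at -2.20 in mouse 202 and -2.11 in mouse 929.

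The VEGFA difference between lung and primary tumor cells differed between models, at an adjusted p of 0.0156 for the interaction (limma), with -2.17 cycles in HCI-001, 0.22 in HCI-002 and -0.45 in HCI-010. Of 100 splits of the 9 mice into 3 sets of 3, the real split included, 8 gave as many genes as the real split, which gave 1. The highest other split also gave 1, so chance could not be excluded for this count.

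For lung against primary tumor, the real labels gave 2 genes. Of 100 swaps of the tissue labels within mice, the real labels included, 1 gave as many, the highest other swap giving 0. Chance alone was thus an unlikely source of the count at this setting. It was not excluded, since 0 genes passed with the exact sign-flip test per gene. Within a model, 4 swaps are too few for a share under 0.05, and the real counts were 1 in HCI-001, 0 in HCI-002 (limma, 3 at an unadjusted p under 0.05) and 2 in HCI-010, with 0 as the highest other in each. Likewise 8 swaps are too few for lymph node against primary tumor (limma, 6 at an unadjusted p under 0.05) and for lung against lymph node (limma, 5), where the real count and the highest other were both 0. Among primary tumors, the real split by model gave 0 genes (limma, 8 at an unadjusted p under 0.05), so that 100 of 100 splits give as many by construction and nothing follows for chance. The highest other split gave 8 genes, which may point to a structure of the samples, in the tumors or in the runs, but no test of such a structure was run and the highest of 99 other splits can also be high by chance.

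Lung cells of HCI-010 lay lower in VIM and EMP1, by a mean difference of -2.88 cycles. Less RNA template in each lung cell would lower other abundant genes too. The median difference of the 11 other genes with a primary level of 4 cycles or more was 0.41 cycles (SD over mice 0.19, with 7 higher and 4 lower). That argues against less template as the whole cause. Lung cells had a median of 54 genes detected against 59.5 in primary tumor cells in mouse 552. The medians were 56 against 58 in mouse 549 and 46.5 in both tissues in D345. Cells of a non-epithelial type among the lung cells would have to lack epithelial genes in about as many cells as lost VIM. The mean share of cells with EPCAM, KRT5 or CDH3 changed by 0.217 points while that with VIM changed by -36.9 points. That argues against such cells as the whole cause. Another epithelial population low in VIM would keep these genes, so this test cannot speak to it. Across 85 other genes, the correlation of a gene with VIM and EMP1 among primary cells and its lung minus primary difference had a Spearman correlation of -0.357. Genes are not independent, and the same primary cells enter both values. A shift of cells along an axis on which many genes vary together from cell to cell would give this sign. Such a shift may account for part of the difference. CDH3 and KRT5 went the other way. Their mean correlations with VIM and EMP1 were 0.134 and 0.158, but they were higher in HCI-010 lung cells, by 0.70 and 0.82 cycles. Whether handling during digestion or the tissue itself moves cells along such an axis stays open, and a biological difference between the tissues was not tested apart from that.

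Of the 22 genes with a Ct in mouse 557 alone, which no comparison used, 1 was detected in at least 50% of its cells.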

How the results depend on the processing

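Settings chosen only after seeing the data were the limit of detection of 34, unmeasured genes at 0, the fits without mice 557 and 769, and the centring of cells for gene lists and for the spread; all others were planned. Over 18 settings and the leave-one-out fits, 320 of 437 values of 21 results kept their direction and their side of the threshold, or, for counts of genes, stayed within 1.5 times. For 19 named genes of lung against primary tumor, 488 of 513 values kept their direction. CDH3 stayed above 0 in 27 of 27 settings and passed in 18, and KRT5 stayed above 0 in 27 of 27 and passed in 6. The cause of a change was not tested except where a setting leaves fewer mice or genes. The planned centring on reference genes, the cells with all reference genes and the reference gene level could not be run, because the panel held none of those genes. Detection limits the results at low levels, since a higher limit counts late cycles that a lower one sets to 0.

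For lung against primary tumor, the count of 2 genes was 1 with a limit of 22, a limit of 26, cells centred on their mean, limma with trend and robust, or without mice 557 and 769. It was 0 with a limit of 28 or 34, the share of cells with detection, the mean over detected cells only, the median over cells, without the cells with the fewest genes, with the resected mouse, and with the exact sign-flip test per gene. Leaving out single mice gave 1 to 2, with 1 without mouse 202, 929, 769, 599, 22, 552 or 549.

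For the difference between models, the count of 1 was 0 with a limit of 22, 26 or 34, with the share of cells, or without mice 557 and 769, 2 with a limit of 28, and 3 with a filter of 20%. Leaving out single mice gave 0 to 6, with 0 without 202, 929 or 557, 2 without 769 and 6 without D345. Within HCI-001 the count of 1 was 0 with the share of cells or a limit of 34 and 2 with a filter of 20%, and leaving out single mice gave 1 to 3 (2 without 929, 3 without D345). Within HCI-002, leaving out single mice gave 0 to 1 (1 without 549). Within HCI-010 the count of 2 was 4 with a limit of 22, 6 with 28 and 8 with 34, 1 with no gene filter or with unmeasured genes at 0, and 0 with the share of cells or weights by the number of cells. Leaving out single mice there gave 0 to 14, with 14 without D345, 1 without 557 and 0 without 202, 929, 22, 552 or 549.

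For lung against lymph node, leaving out single mice gave 0 to 1 genes (1 without 549), and for lymph node against primary tumor the count was 0 in all 22 settings. For blood against primary tumor the count of 2 was 0 with a limit of 22, the share of cells or weights by the number of cells, 1 with centred cells or without mice 557 and 769, and 6 with a limit of 34. Leaving out single mice gave 0 to 2 (0 without 552 or 549, 1 without 929 or 769). Without 769 or 599, blood came from 1 mouse, which is assumed to vary like the other tissues, and the minimum of 2 mice per gene was lowered to 1. For the primary tumors of the 3 models, leaving out single mice gave 0 to 2 (1 without 929 or 599, 2 without 557).

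Without the mouse as a block (no replicate block, model as covariate), 0 genes passed limma for lung against primary tumor, 0 for the difference between models, 0 within HCI-001, 0 within HCI-010 and 0 for blood, and no other count changed. The pairing leaves the differences between mice and between runs out of the error. The lung set of 8 of 9 mice, all but mouse 552, correlated best with the primary set of its own mouse, which a shared run alone could also give.

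With each cell centred on its mean, the shift was 0.23 for the stem cell list (exact sign-flip adjusted p = 0.0977), 0.15 for Notch, Wnt and Hedgehog (0.449), 0.36 for quiescence (0.156), 0.26 for survival (0.449) and 0.15 for stromal markers (0.458), none past the threshold, and it was -0.0409 for EMT and -0.0865 for proliferation, both reversed. With the resected mouse, the Notch, Wnt and Hedgehog list (0.24, adjusted p = 0.0635) and the survival list (0.32, 0.133) did not pass, and proliferation was -0.0030. With a limit of 22, stromal markers were at 0.15 (0.0521) and proliferation at -0.0132. With a limit of 34, survival was at 0.69 (0.0625) and luminal at 0.0783. Survival did not pass without the cells with the fewest genes (0.37, 0.109) or with unmeasured genes at 0 (0.30, 0.0547). Without mice 557 and 769, stromal markers were at 0.36 (0.0625) and proliferation at -0.0167. Leaving out single mice gave -0.12 to 0.0345 for luminal (above 0 without 552), -0.0353 to 0.18 for proliferation (below 0 without 599), 0.42 to 0.55 for quiescence, 0.24 to 0.45 for survival and 0.23 to 0.32 for stromal markers. The adjusted p missed the threshold for quiescence and for stromal markers without 929, 599, 22, 552, 549 or D345, and for survival without any of these or without 202.

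The spread between cells was -0.0667 with a limit of 34, and leaving out single mice gave -0.0152 to 0.11 (below 0 without 599). Genes detected per cell differed by -0.75 with the resected mouse, by -0.857 without mice 557 and 769, and by 3.06 with a limit of 34, where the difference passed (exact sign-flip p = 0.0469). Leaving out single mice gave -0.688 to 0.75 (below 0 without 557 or 599).

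The named genes below changed sign, and none passed in the settings named. MYC was 0.0449 as a share of cells and 0.33 with a limit of 34, and leaving out single mice gave -0.52 to 0.0783 (above 0 without 552). CDH1 was 0.0618 over detected cells, and leaving out single mice gave -0.34 to 0.0369 (above 0 without 202). KRT8 was 0.0220 and SOX2 -0.12 over detected cells. SNAI2 was -0.11 with a limit of 22, -0.30 over detected cells, -0.13 with centred cells, -0.0661 without the cells with the fewest genes, -0.0125 with the resected mouse, -0.0760 without mice 557 and 769, and -0.12 to 0.20 without single mice (below 0 without 202, 929, 769 or D345). TGFBR3 was 0.0054 with a limit of 22 or 26, 0.0464 with 28, 0.31 with 34, 0.0016 as a share of cells, 0.19 over detected cells, and -0.0817 to 0.0631 without single mice (above 0 without 202 or 552).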

Other observations

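The gene sets and the tests of explanations in this part were chosen only after the values were seen.

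A set of 6 genes varied together from cell to cell within a tissue, among them VIM and EMP1, the 2 genes past the threshold in HCI-010 lung cells. For VIM, EMP1, ITGB1, CAV2, CD44 and MYC, which span cytoskeleton, adhesion, caveolae and growth control, the mean correlation between pairs of these 6 genes, over the cells of a mouse with tissue means removed, ran from 0.153 to 0.619 over the 12 mice. The median over all gene pairs ran from 0.0221 to 0.187, and the 6 genes lay above it in 12 of 12 mice. The mean over mice was 0.418. The value was highest in mouse 453 (0.619 against 0.0303 over all pairs), and in mouse 769 (0.153 against 0.124) and mouse 510 (0.220 against 0.187) the 6 genes hardly exceeded the other pairs. They were chosen for this pattern, so the 12 of 12 is no test of it. Cells are not independent samples, so no p was computed.

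Mouse 557 of HCI-001 was the 1 mouse with a Ct for the keratin genes KRT17 and KRT18. KRT17 was detected in 43.6% of its cells, KRT18 in 38.3%, and SPARC, a matrix protein gene, in 31.9%. KRT18 was detected in 43.8% of lung cells and 29.8% of primary tumor cells, and KRT17 in 50% and 46.8%. KRT14 was given a Ct in that mouse but was detected at a Ct of 24 or below in 0% of cells. RB1, measured in mouse 599 alone, was detected in 9.52% of cells.

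Most of the 24 genes with no Ct in mouse 557 but a Ct in at least 8 other mice were rarely detected in mouse 769 of HCI-002. Their median share of cells was 1.18%, against 32.0% in the 2 other HCI-002 mice with primary tumors. These shares count a gene with no Ct in a mouse as not detected there, unlike the comparisons between tissues. In mouse 769, 19 of the 24 genes had a Ct, so the median over measured genes alone would be higher. Of the 24 genes, 20 were detected in under 10% of its cells, but MTOR in 57.6% and IGFBP6 in 41.2%. Poor cells would lower other genes too, but over the other 67 genes the median share differed by 0.709 points from those mice, which argues against that explanation. The low share could come from another assay set or preamplification pool in the runs of mice 557 and 769, as a hypothesis. MTOR and IGFBP6 go against a pool in mouse 769 that lacked all 24 genes. No biological explanation was tested, and a run and its mouse cannot be told apart.

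EGFR, a growth factor receptor gene, reached mean primary tumor levels from 14.3 to 18.9 cycles in 7 mice, which is a Ct below 10, but not in mouse 769 (6.48) or mouse 557 (2.61). The largest difference between mice of the same model was 15.9 cycles, in line with an EGFR assay that differed between runs. The model means differed by at most 7.04 cycles, less than mice within a model, which argues against a difference between the models as the whole cause. Mouse 202 had no EGFR Ct, so the HCI-001 mean rests on 2 mice. Within a mouse the lung minus primary difference was 0.20 cycles (SE 0.22, adjusted p = 0.628, limma). A difference between the tumors of single mice stays open.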
